A study of Homo sapiens with 12 samples.

How the data were processed

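RNA and H3K4me3 chromatin of HCT116 cells were compared between medium with methionine (+MET) and without it (-MET), both for 24 h by the labels. Of the 12 samples, 8 had tables to work from: 2 polyadenylated RNA libraries and 2 H3K4me3 ChIP libraries per condition. The 4 input DNA libraries were not analysed here. Groups came from the sample titles. The labels give both conditions replicate numbers 1 and 2 and do not say that equal numbers belong together.

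Per the submitters' processing notes, base calling used CASAVA 1.4, the reads were placed on hg19, and MACS2, HTSeq, edgeR and DESeq2 were used, without versions. The aligner, the gene annotation and the thresholds are not given in the sources used here. The deposited RNA tables hold HTSeq read counts per gene symbol, whole numbers with no normalization, 1 table per library. The deposited peak lists were made by the authors with MACS2, 1 per library, and give a peak length in bp, equal to end minus start plus 1. Per the file headers they also give a signal column of tags, which is the caller's pileup height over the peak and is fractional. Per the file headers they give the fold enrichment, a ratio over the caller's local background, and -log10 p and -log10 q values. Whether the input libraries served as the control of the caller is not given in the sources used here. The deposited H3K4me3 gene tables hold 1 signal value per gene and library: 100% of these values also occur among the pileup heights of the peaks of the same library. They are therefore peak heights and not counts, and no scaling between libraries is stated.

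Of the 23368 RNA entries, 2 lacked a value and were left out, 28 names had been turned into dates and were kept as they stood, and 2 names were repeated. Symbols were looked up in a RefSeq table for current names and gene type only. The H3K4me3 gene tables held 10915 entries for 10361 genes. An entry was matched to the overlapping peaks that carried its height in all 4 libraries, which gave 1 set of peaks for 10893 entries, none for 22 and several for 0. A gene named in several entries, as in 554 of them, took the mean over its distinct values. The width of a gene was the total length of its distinct matched peaks in each library.

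RNA counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, and the quasi-likelihood F test of -MET against +MET, with Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 folds are the fold divided by the square root of F. For genes named by the rule below with at most 3 counts in any library, the ratio of summed CPM is given. It has an exact 95% interval from the binomial split of the counts. Such intervals cover counting error only. H3K4me3 heights were tested with limma 3.58.1 (trend) on log2 of the value plus 1, the test planned for a table that does not hold counts, and widths on log2 of the length. On simulated data of the same size, edgeR found 44% of 100 genes changed by 1 and 91% of 100 changed by 2 on the log2 scale, and called 0.0362% of unchanged genes. For limma these values were 0%, 3% and 0% for heights and 41%, 94% and 0.0787% for widths.

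The 29 gene lists were tested with camera (limma) at a preset correlation of 0.01, two-sided, on log2 CPM with a prior count of 3 for RNA. Lists with under 5 tested members had no set test. Camera with a correlation estimated from each list, and fry, were run beside it. On simulated RNA a list of 30 genes shifted by 1 had an adjusted p of 3.49e-35 at the preset correlation, 0.316 with an estimated correlation and 0.173 with fry, and 0 of 50 unshifted lists were called by any of them. An estimated correlation thus had little power in this simulation of 2 libraries per condition. Its genes were drawn independently, so it cannot show how often the preset correlation calls unchanged lists whose genes move together. Its p-values were also adjusted over more lists than in the data. For H3K4me3, fry ran on values centred per library, and list medians of width use centred widths. The 4 lists of the closing part were chosen after the values were seen.

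Peak number, median width and median fold enrichment were compared with a two-sided exact permutation test, which cannot go below 0.3333 with 2 against 2 libraries. Overlaps of at least 1 bp were found with bedtools 2.31.1. Correlations across genes had 100000 permutations, and overlaps of calls used Fisher's exact test. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A +MET library was compared with the other by the percentile of a list's median difference among 10000 random lists matched on expression. The background under each peak was inferred by taking the fold enrichment as the height plus 1 over the background plus 1, and the lowest such value of a library stood for its depth.

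The comparisons, their tests, the gene lists and the rule for named genes were set before the data were examined. The rule named, for each assay, the 8 genes with the highest and the 8 with the lowest fold among those with an adjusted p under 0.05, a mean log2 CPM of at least 3 and both -MET libraries on one side of both +MET libraries, without pseudogenes, antisense and unnamed features. For heights the mean log2 CPM was not defined and that part was left out. It added up to 4 members with the smallest adjusted p from each list called or with at least 3 passing members, and all members of the methionine, H3K4 and other-cell-type lists. Across assays it named genes passing in both, and for peaks the 5 widest shared by both +MET libraries. This gave 158 genes in RNA. Of all tested genes, 3377 met the thresholds of the first part, before the choice of 8 in each direction. Genes with narrower peaks are examples chosen after their values were seen.

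Alternatives for RNA were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors, library totals, 2 other count filters, an adjusted p under 0.1, the replicate number as a block, and leaving out each library. The planned count-based alternatives for H3K4me3 (size factors, library totals, count filters and DESeq2) were not run because its table is not counts. In their place stood settings chosen after seeing the data: centring on the median, scaling to the same total, a pseudocount of 5, a mean of at least 20 tags, and width in place of height. For peaks the alternatives were q under 1e-10, chromosomes 1 to 22 and X, merging within 1000 bp, means, equal numbers of top peaks, covering 50% of both peaks, and classes from the other +MET library. A fit that leaves out a library keeps 1 sample in that condition and assumes that it varies like the others.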

Results

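HCT116 cells, an established human colon cancer line, were kept for 24 h in medium with methionine (+MET) or without it (-MET). Methionine is the precursor of S-adenosylmethionine, the methyl donor used by histone methyltransferases. The series compared H3K4me3, the trimethylation of histone H3 at lysine 4 that marks active promoters, and polyadenylated RNA between these conditions. Each assay had 2 libraries per condition. The RNA tables held 15619046 and 17345705 counts in +MET replicates 1 and 2, and 14194175 and 16731387 counts in -MET replicates 1 and 2. They showed at least 1 count for 15915, 16490, 17023 and 17370 genes in the same order. The 10 genes with the most counts took 4.34%, 3.47%, 3.36% and 3.50% of each library. The H3K4me3 data were 1 peak list and 1 gene table per library, and their read depth is not given in the sources used here. The 4 input DNA libraries were not analysed here. The labels put all RNA libraries at 24 h in +MET or -MET medium, whereas the names of the RNA tables carry 0 h for +MET and 24 h for -MET. It was not settled whether the +MET RNA was collected at the start or beside the -MET RNA. Nothing says that replicates came from separate cultures, so the p-values measure only the spread between these libraries.

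In RNA, chemokine and matrix genes were among those with the highest folds in -MET, and genes of DNA replication and its regulators were among the lowest. CCL20, a chemokine, had 1 and 1 counts in the +MET libraries and 266 and 341 in the -MET libraries, a ratio of 296 (95% exact counting interval 81.5 to 2446). TNC, which encodes the matrix protein tenascin C, had 2 and 1 counts against 244 and 351, a ratio of 193 (65.8 to 939). CCL20 and TNC passed the count filter through the -MET libraries alone, so they could only rise. Log2 folds of -MET over +MET are given with their standard error, from 2 libraries per condition. The linker histone gene HIST1H1C rose by 6.26 ± 0.38, the chemokine genes IL8 (now CXCL8) by 5.60 ± 0.28 and CXCL1 by 5.56 ± 0.36. TEX14 rose by 5.24 ± 0.24, the cornified envelope gene SPRR2D by 5.10 ± 0.44 and CCDC80 by 4.99 ± 0.34. Among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and both -MET libraries below both +MET libraries, GINS2, a subunit of the replicative helicase complex, had the lowest fold, -3.86 ± 0.24, from a mean of 120 to 8.27 CPM, the counts scaled to library size. CCNE2, which encodes cyclin E2, changed by -3.54 ± 0.45, the PCNA-binding factor gene KIAA0101 by -3.53 ± 0.17 and the transcription factor gene E2F2 by -3.08 ± 0.24. LRRC45, TMSB15A, FAM20C and ZNF367 changed by -3.70 ± 0.24, -3.58 ± 0.33, -3.40 ± 0.26 and -3.24 ± 0.23. These 16 genes had edgeR adjusted p from 0.00203 to 0.00473. The RNA tables give gene symbols and no positions.

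Of 14012 genes tested with edgeR, 4127 passed an adjusted p of 0.05, with 1943 higher and 2184 lower in -MET. At least 2-fold changes were seen in 1264 of the higher and 1178 of the lower genes, and 6101 genes passed an unadjusted p of 0.05. Scaling by library totals alone moved the median fold of all genes by 0.13 on the log2 scale and called 2338 genes higher and 1675 lower, so the balance of the directions depended on the scaling. The count also fell without either -MET library and rose without either +MET library. A fit without 1 library takes its spread from the condition that keeps both. The root mean square difference of log2 CPM was 0.631 between the +MET libraries and 0.284 between the -MET libraries. Counts of genes passing without a library, given below, therefore reflect that spread as well as the library left out.

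Genes of cell division fell together. All 30 measured genes of DNA replication and the G1/S transition fell, with a median of -2.26, and all 30 also passed when adjusted over the list alone. MCM3, a subunit of the replicative helicase, changed by -2.42 ± 0.14 on the log2 scale, the sliding clamp gene PCNA by -2.19 ± 0.14, and the G1/S transcription factor gene E2F1 by -3.01 ± 0.20. Of 30 genes of mitosis and G2/M, 27 fell, 0 rose and 3 did not pass, with a median of -1.44; 28 fell when adjusted over the list alone. CCNA2, which encodes cyclin A2, changed by -2.49 ± 0.18, CKS2 by -1.97 ± 0.16, the cyclin-dependent kinase gene CDK1 by -1.77 ± 0.17, and the survivin gene BIRC5 by -1.61 ± 0.16. The lists were compared with all other genes by camera at a preset correlation, where DNA replication had an adjusted p of 3.14e-19 and mitosis 2.85e-14. Their adjusted p was 0.562 and 0.576 with an estimated correlation. None of the 13 fixed lists called at the preset correlation held with an estimated one, where 1 of 25 lists had an unadjusted p under 0.05. Without -MET replicate 2 the mitosis genes that fell numbered 17.

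**Figure D1:**
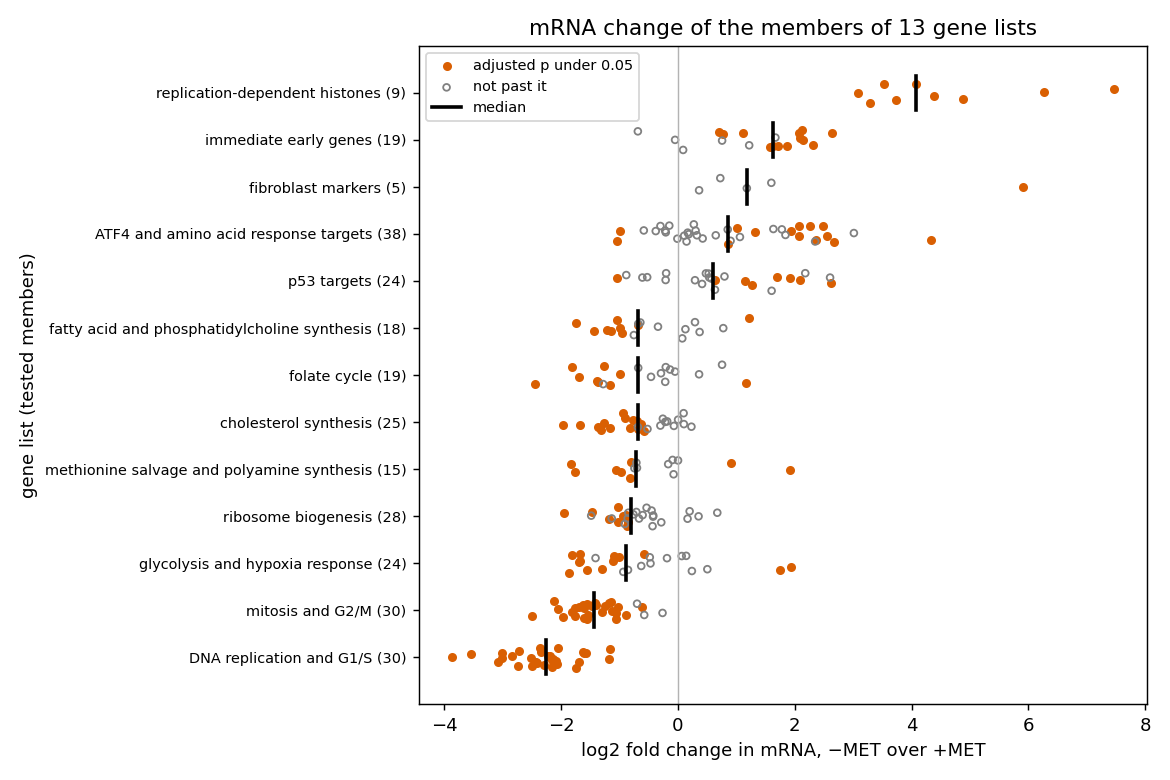
Log2 fold change of -MET over +MET (x axis) for each tested member (points) of the 13 fixed gene lists that camera called (y axis); filled orange points passed edgeR's adjusted p of 0.05, open grey ones did not, and a black line marks each list's median. DNA replication has the lowest median, -2.26, and replication-dependent histones the highest, 4.08.

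Replication-dependent histone genes went the other way from the replication genes. Of the 20 genes of the list, 9 passed the count filter. All 9 rose, in edgeR over all genes and when adjusted over the list alone. HIST1H1E, HIST1H4H and HIST1H2BJ had at most 3 counts in each +MET library. They passed the filter through the -MET libraries alone, so they could only rise, and the counts and set test of the list rest partly on them. HIST1H2BK rose by 3.08 ± 0.32 and HIST1H2BD by 3.52 ± 0.42, beside HIST1H1C above. HIST1H1E had 1 and 2 counts in +MET and 34 and 66 in -MET, a ratio of 32.5 (95% exact counting interval 10.8 to 160). The median of the list was 4.08, or 3.52 with the 3 members of lowest counts at the bound of their interval. The share of all counts on histone genes was 0.00141% and 0.00191% in the +MET libraries and 0.0240% and 0.0446% in the -MET libraries. These libraries were made from polyadenylated RNA, and most mRNAs of this class lack a poly(A) tail. The camera adjusted p was 2.52e-06, and 0.602 with an estimated correlation.

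Some of the stress genes rose in -MET. Of 38 measured targets of ATF4, the transcription factor of the amino acid response, 12 rose, 2 fell and 24 did not pass. Their median was 0.86, or 0.32 without +MET replicate 1 and 1.38 without +MET replicate 2. The counts adjusted over the list alone were the same 12 and 2. PPP1R15A, a phosphatase subunit that reverses the translation block, rose by 4.33 ± 0.24, the transcription factor gene CEBPG by 2.36 ± 0.23 and the stanniocalcin gene STC2 by 1.32 ± 0.14. Of 24 p53 targets, 7 rose and 1 fell, or 8 and 2 adjusted over the list alone, with a median of 0.60. GADD45A rose by 2.63 ± 0.30, the death receptor gene TNFRSF10B by 2.10 ± 0.26, PLK3 by 1.91 ± 0.19 and ZMAT3 by 1.26 ± 0.20. Of 19 immediate early genes, 13 rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 1.64. The AP-1 genes JUN and JUNB rose by 2.63 ± 0.19 and 2.12 ± 0.21, EGR1 by 2.32 ± 0.22 and IER2 by 2.14 ± 0.16. Camera gave adjusted p of 5.96e-04 for ATF4 targets, 0.00414 for p53 targets and 3.20e-06 for immediate early genes. With an estimated correlation the adjusted p were 0.686, 0.679 and 0.562. With fry they were 0.233, 0.118 and 0.0334.

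The +MET libraries differed from each other in part of these genes. Relative to +MET replicate 1, the median ATF4 target was higher by 1.32 on the log2 scale in +MET replicate 2, by 1.41 in -MET replicate 1 and by 1.29 in -MET replicate 2. CHAC1, an ATF4 target that degrades glutathione, stood at 1.40 and 48.4 CPM in +MET replicates 1 and 2 and at 108 and 148 CPM in -MET. DDIT4, an inhibitor of mTORC1, stood at 15.2, 199.57, 817 and 920 CPM, and TRIB3 at 47.7, 204, 631 and 578 CPM, in the same order. For the median gene of DNA replication the differences from +MET replicate 1 were -0.30, -2.21 and -2.47, and for immediate early genes -0.02, 1.60 and 1.91. Across genes, log2 CPM had a Pearson r of 0.974 between the +MET libraries and 0.993 between the -MET libraries. Without +MET replicate 2, 32 ATF4 targets rose and 3 fell, and 16 p53 targets rose and 3 fell. Without +MET replicate 1 these numbers were 18 and 9 for ATF4 targets and 15 and 4 for p53 targets, and 18 immediate early genes rose and 0 fell, against 16 and 3 without +MET replicate 2. Without -MET replicate 1 and without -MET replicate 2 the immediate early genes that rose numbered 8 and 6.

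**Figure D2:**
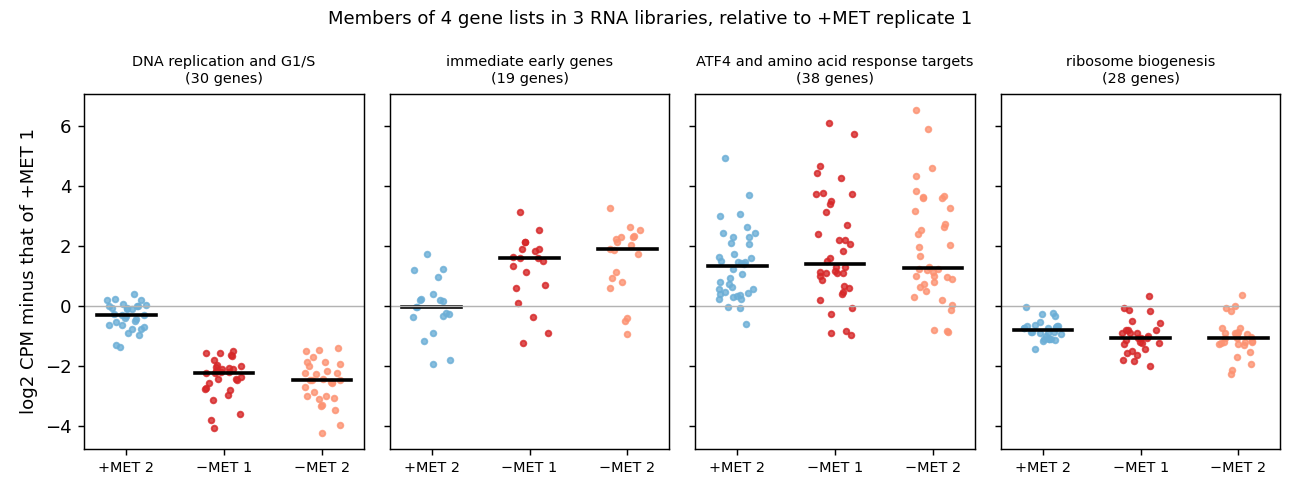
Log2 CPM minus that of +MET replicate 1 (y axis) for each member (points) of 4 fixed lists in +MET replicate 2 and both -MET libraries (x axis), with a black line at each median. In +MET replicate 2 the ATF4 targets lie at 1.32, near both -MET libraries, whereas DNA replication lies at -0.30 and immediate early genes at -0.02.

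Some genes of lipid synthesis, of glycolysis and the hypoxia response, and of ribosome biogenesis fell. Of 25 genes of cholesterol synthesis, 14 fell and 0 rose, or 16 and 0 adjusted over the list alone, with a median of -0.68. ACAT2 changed by -1.96 ± 0.17, INSIG1 by -1.67 ± 0.21 and FDPS by -1.26 ± 0.16. Of 18 genes of fatty acid and phosphatidylcholine synthesis, 8 fell and 1 rose, or 10 and 1 adjusted over the list alone, with a median of -0.68; FADS1 changed by -1.44 ± 0.23, ACLY by -1.21 ± 0.13, PCYT2 by -1.15 ± 0.18 and the fatty acid synthase gene FASN by -0.95 ± 0.15. Of 24 genes of glycolysis and the hypoxia response, 11 fell and 2 rose, or 14 and 2 adjusted over the list alone, with a median of -0.89. LDHA, the lactate dehydrogenase gene, changed by -1.87 ± 0.14, PFKL by -1.81 ± 0.15, GPI by -1.69 ± 0.13 and PGK1 by -1.68 ± 0.14. Of 28 genes of ribosome biogenesis, 9 fell and 0 rose, or 13 and 0 adjusted over the list alone. Their median was -0.80, or -0.29 without +MET replicate 1 and -1.10 without +MET replicate 2. NPM1 changed by -1.95 ± 0.16, BOP1 by -1.02 ± 0.20, WDR12 by -0.93 ± 0.16 and the fibrillarin gene FBL by -0.85 ± 0.14. The camera adjusted p were 1.49e-04 for cholesterol synthesis, 0.0255 for fatty acids, 5.79e-04 for glycolysis and 5.96e-04 for ribosome biogenesis. With an estimated correlation the adjusted p were 0.562, 0.623, 0.562 and 0.686. With fry they were 0.00546, 0.0389, 0.0274 and 0.233. The median ribosome biogenesis gene was lower in +MET replicate 2 than in +MET replicate 1 as well (-0.80 on the log2 scale), and the list's adjusted p was 0.101 without +MET replicate 1; that of fatty acids was 0.0590 without +MET replicate 2. Without -MET replicate 1 and without -MET replicate 2 the genes that fell numbered 4 and 3 for cholesterol synthesis, 4 and 2 for fatty acids, and 3 and 3 for ribosome biogenesis. Without +MET replicate 1 and without +MET replicate 2, 14 and 24 ribosome biogenesis genes and 17 and 16 glycolysis genes fell. Scaled by library totals alone, 9 cholesterol genes fell, and DESeq2 called 16 ribosome biogenesis genes lower and 1 higher.

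The folate and methionine pathways moved in part. Of 19 folate cycle genes, 8 fell and 1 rose, or 9 and 2 adjusted over the list alone, with a median of -0.68. TYMS, the thymidylate synthase gene, changed by -2.44 ± 0.14, MTHFD1 by -1.68 ± 0.16 and SHMT1 by -1.37 ± 0.18. Of 15 genes of methionine salvage and polyamine synthesis, 6 fell and 2 rose, or 9 and 2 adjusted over the list alone. Their median was -0.71, or -0.37 without +MET replicate 1. SMS, the spermine synthase gene, changed by -1.83 ± 0.16 and MTAP, which starts the salvage of methionine, by -1.75 ± 0.22. The salvage genes ADI1, ENOPH1 and APIP changed by -1.065 ± 0.20, -0.97 ± 0.18 and -0.82 ± 0.20, and the antizyme gene OAZ1 by -0.80 ± 0.16. The polyamine catabolic genes SMOX and SAT1 rose by 1.93 ± 0.32 and 0.90 ± 0.17. ODC1 and AMD1, which encode the regulated decarboxylases of polyamine synthesis, stood at -0.09 ± 0.16 and 0.00 ± 0.25 and did not pass, nor did MRI1 at -0.74, AZIN1 at -0.71, SRM at -0.70, OAZ2 at -0.17 and PAOX at -0.07. Camera gave adjusted p of 0.00484 for the folate cycle and 0.0299 for salvage and polyamines, and 0.562 for each with an estimated correlation; without +MET replicate 1 the salvage list had an adjusted p of 0.0742. Without -MET replicate 1 and without -MET replicate 2, 6 and 5 folate genes and 2 and 2 salvage genes fell, and without +MET replicate 1, 10 salvage genes fell.

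Of 10 methionine cycle and transsulfuration genes, 2 rose, 2 fell and 6 did not pass, with the same counts adjusted over the list alone. MAT2A, the main S-adenosylmethionine synthetase gene outside the liver, rose by 0.95 ± 0.19. BHMT, a remethylating enzyme gene, had 0 and 2 counts in +MET and 27 and 40 in -MET. Its ratio was 32.6 (95% exact counting interval 8.68 to 275). BHMT passed the count filter through the -MET libraries alone, so it could only rise. AHCY, which clears S-adenosylhomocysteine, changed by -1.03 ± 0.15 and the methionine synthase gene MTR by -0.96 ± 0.16. MAT1A stood at 0.56, AHCYL2 at 0.18, CTH at -0.15, AHCYL1 at -0.16, MTRR at -0.20 and MAT2B at -0.29, and none of these passed. The median of the list was -0.16, also with BHMT at the bound of its interval, the mean 0.38, and camera's direction down with an adjusted p of 0.985, or 0.986 with an estimated correlation. Of these genes 4 fell without +MET replicate 1, 3 without +MET replicate 2 and 1 without either -MET library.

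Enzymes that write and erase H3K4 methylation changed in both directions. Of 20 H3K4 methyltransferase genes and subunits, 5 rose, 4 fell and 11 did not pass, or 6 and 4 adjusted over the list alone, with a median of -0.15. Scaled by library totals alone, 7 rose and 2 fell, with a median of -0.01. The methyltransferase gene SETD1B rose by 0.88 ± 0.17, MLL3 by 0.65 ± 0.19, and the complex subunit genes KDM6A and NCOA6 by 0.71 ± 0.18 and 0.68 ± 0.16. WDR5, a core subunit of the SET1 and MLL complexes, changed by -1.04 ± 0.29, PAXIP1 by -0.94 ± 0.19, HCFC1 by -0.83 ± 0.24 and DPY30 by -0.66 ± 0.18. MLL, SETD1A, ASH2L, RBBP5, CXXC1, WDR82, MEN1, SMYD3, SETD7 and ASH1L stood at 0.09, 0.26, -0.45, -0.07, -0.36, -0.58, -0.23, -0.61, -0.41 and 0.76 and did not pass. The symbols MLL2 and MLL4 have each been used for both of a pair of paralogs; here MLL2 rose by 0.70 ± 0.21 and MLL4 stood at 0.52 ± 0.21 and did not pass. Of 10 H3K4 demethylase genes and cofactors, 2 rose and 2 fell, also adjusted over the list alone, with a median of 0.23. KDM5B and KDM5C rose by 1.95 ± 0.33 and 1.17 ± 0.15, whereas KDM1A and KDM2B changed by -1.13 ± 0.14 and -1.24 ± 0.23. KDM1B, KDM5A, C14orf169, RCOR1, RCOR2 and RCOR3 stood at 0.19, 0.27, -0.01, 0.30, -0.42 and 0.48 and did not pass. Neither list was called by camera, with adjusted p of 0.899 and 0.556, or 0.986 and 0.786 with an estimated correlation. Demethylase genes that rose and fell numbered 4 and 3 without +MET replicate 1, 4 and 2 without +MET replicate 2, and 2 and 1 without either -MET library. Without -MET replicate 1, 0 methyltransferase genes passed edgeR, with 1 higher and 3 lower at an unadjusted p under 0.05, and without -MET replicate 2, 0 passed, with 4 higher and 2 lower. Without +MET replicate 1 there were 8 higher and 6 lower, and without +MET replicate 2 there were 6 higher and 10 lower. Of 28 other histone, DNA and protein methyltransferase genes, 9 fell and 2 rose, or 11 and 2 adjusted over the list alone, with a median of -0.05, or 0.08 scaled by library totals, and a mean of -0.21. PRMT7 changed by -1.31 ± 0.21, SUV39H1 by -1.25 ± 0.21, PRMT1 by -0.89 ± 0.14 and DNMT1 by -0.83 ± 0.14; the camera adjusted p was 0.254, or 0.686 with an estimated correlation. Of these 28 genes 1 fell and 0 rose without -MET replicate 1, with 6 lower and 1 higher at an unadjusted p under 0.05, and the counts were the same without -MET replicate 2. Without +MET replicate 1 and without +MET replicate 2, 12 and 11 fell and 9 and 4 rose.

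Other fixed lists held strong single changes without a call by camera. Of 25 lysosome and autophagy genes, 6 rose and 3 fell, also adjusted over the list alone (median 0.21, adjusted p 0.254, or 0.686 with an estimated correlation). The autophagy genes MAP1LC3B and SQSTM1 rose by 2.78 ± 0.29 and 1.89 ± 0.17 and the lysosomal transcription factor gene TFE3 by 2.02 ± 0.15, whereas ATP6V1H changed by -1.31 ± 0.18. Of 18 antioxidant genes, 6 rose and 4 fell, or 7 and 5 adjusted over the list alone (median 0.35, adjusted p 0.140, or 0.686). The ferritin genes FTH1 and FTL rose by 1.87 ± 0.13 and 1.18 ± 0.13, and the pentose phosphate genes TALDO1 and TKT changed by -1.32 ± 0.15 and -1.20 ± 0.13. Of 20 endoplasmic reticulum stress genes, 6 rose and 5 fell, also adjusted over the list alone (median 0.08, adjusted p 0.556, or 0.727). ERN1 rose by 2.12 ± 0.31 and the chaperone genes HSPA5 and HYOU1 by 1.68 ± 0.12 and 1.10 ± 0.15, whereas HSP90B1 changed by -0.83 ± 0.12. Of 15 interferon response genes, 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (median 0.77, adjusted p 0.105, or 0.684), with IRF7 rising by 3.57 ± 0.30, IFIT2 by 1.96 ± 0.45 and IRF9 by 1.45 ± 0.26 and OAS3 changing by -1.02 ± 0.15. Of 19 aminoacyl-tRNA synthetase genes, 1 rose and 4 fell, also adjusted over the list alone (median -0.07, or 0.05 scaled by library totals, adjusted p 0.556, or 0.786). SARS rose by 1.30 ± 0.23, and QARS, DARS and KARS changed by -1.14 ± 0.14, -0.87 ± 0.15 and -0.76 ± 0.14. Endoplasmic reticulum stress genes that rose and fell numbered 3 and 1 without -MET replicate 1, and 4 and 1 without -MET replicate 2. In the same 2 fits 4 and 4 lysosome genes and 2 and 1 interferon genes rose and none of either list fell, and 2 and 2 synthetase genes fell. Without +MET replicate 1 and without +MET replicate 2, 7 and 14 lysosome genes, 9 and 10 antioxidant genes, 8 and 8 interferon genes and 2 and 7 synthetase genes rose, and 7 and 4 lysosome genes, 6 and 8 endoplasmic reticulum stress genes and 9 and 7 synthetase genes fell. Scaled by library totals alone, 7 endoplasmic reticulum stress genes rose and 3 fell.

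The lists tied to colon cancer were not called by camera either. Of 31 colorectal cancer driver genes, 7 fell and 2 rose, or 8 and 2 adjusted over the list alone (median -0.07, or 0.05 scaled by library totals, camera adjusted p 0.319, or 0.686 with an estimated correlation). The mismatch repair gene MSH6 changed by -2.09 ± 0.23, AKT1 by -1.15 ± 0.15 and RHOA by -0.59 ± 0.13. Of 15 MYC and Wnt target genes, 2 fell and 1 rose, also adjusted over the list alone (median -0.44, adjusted p 0.254, or 0.684). The Wnt target AXIN2 changed by -1.76 ± 0.28 and TCF7 by -0.86 ± 0.17, and EPHB2 rose by 0.80 ± 0.19. Of 12 colon epithelial genes, 2 rose and 1 fell, also adjusted over the list alone (median 0.37, adjusted p 0.497, or 0.722). That median turned to -0.14 without -MET replicate 2. The junction genes CDH1 and CLDN7 rose by 1.58 ± 0.19 and 1.10 ± 0.21, and the keratin gene KRT19 changed by -0.63 ± 0.13. Driver genes that fell numbered 4 and 3 without -MET replicate 1 and without -MET replicate 2, and 0 rose; without +MET replicate 1 and without +MET replicate 2, 12 and 12 fell and 7 and 9 rose. Library totals alone gave 5 lower and 4 higher driver genes. In the fits without a +MET library 5 and 8 MYC and Wnt targets fell and 2 and 3 rose, and 5 and 5 colon epithelial genes rose and 2 and 3 fell. In the fits without a -MET library 1 and 1 MYC and Wnt targets fell and 0 rose, and 3 and 1 colon epithelial genes rose and 0 fell. Without +MET replicate 2, camera called the lysosome, antioxidant, interferon and colon epithelial lists higher, with adjusted p of 0.00812, 0.00910, 0.0156 and 0.00910. The interferon list was also called higher without -MET replicate 1, at 0.0261, and in 1 of 5 settings of scaling, count filter or replicate block, and the antioxidant list was called higher without -MET replicate 2, at 0.0179.

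Markers of other cell types were scarce, and those that passed were higher in -MET. THY1, KDR, VWF and CSF1R had too few +MET counts to pass the count filter without the -MET libraries. They could hardly have come out lower, so their direction and the fibroblast set test below rest partly on that filter. Of 5 fibroblast markers, 1 rose, or 3 adjusted over the list alone: THY1, with 0 and 2 counts in +MET and 77 and 57 in -MET, had a ratio of 65.2 (95% exact counting interval 17.7 to 544). COL1A1 stood at 1.60, FBN1 at 1.18 and VIM at 0.73 and did not pass. PDGFRB, with 2 and 12 counts in +MET and 10 and 8 in -MET, had a ratio of 1.252 (0.588 to 2.72). The list had a median of 1.18, also with THY1 at the bound of its interval. Its camera adjusted p was 0.0299, or 0.679 with an estimated correlation, and its fry adjusted p was 0.116. That call was lost without +MET replicate 1, at 0.0740. Fibroblast markers that rose numbered 4 and 4 without +MET replicates 1 and 2, and 2 and 1 without -MET replicates 1 and 2. Of 4 endothelial markers, 3 rose, also adjusted over the list alone. ESAM rose by 1.06 ± 0.25, KDR had a ratio of 5.16 (2.60 to 11.4) and VWF one of 4.10 (2.26 to 7.96), and ENG stood at -0.48 ± 0.56. In +MET replicates 1 and 2 KDR had 2 and 8 counts and VWF 3 and 11, a spread that these intervals leave out. DESeq2 called 1 of these 4, and without either -MET library edgeR called 0, with 1 and 3 at an unadjusted p under 0.05. Of 2 blood markers, 1 rose, or 2 adjusted over the list alone: CD68, a lysosomal protein gene, rose by 1.42 ± 0.30. CSF1R, with 2 and 8 counts in +MET and 21 and 16 in -MET, had a ratio of 3.60 (1.76 to 8.12). Without either -MET library 0 blood markers passed, with 1 at an unadjusted p under 0.05, and without +MET replicate 2 both passed. Of 4 metallothionein genes, 1 rose, or 2 adjusted over the list alone, and 0 of the 13 mitochondrially encoded genes were in the RNA tables. Lists with fewer than 5 tested genes had no set test.

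H3K4me3 peaks were narrower and less enriched in the -MET libraries. The median peak width was 1739 and 1781 bp in +MET and 1121 and 1456 bp in -MET, a difference of the means of -471.5 bp. The median fold enrichment was 10.3 and 11.5 in +MET and 4.30 and 9.59 in -MET, a difference of -3.96. Peaks numbered 16729 and 17448 in +MET and 13712 and 17095 in -MET, a difference of -1685, and covered 28.9, 30.9, 15.9 and 24.9 Mb. Broad peaks over 4000 bp made up 1.93% and 2.54% of peaks in +MET and 0.219% and 0.907% in -MET. In exact permutation tests the two-sided p was 0.3333 for width and enrichment, the smallest that 2 against 2 libraries allow, and 0.667 for number; adjusted over these 3 tests they were 0.5, 0.5 and 0.667. The size of each difference rested on -MET replicate 1. Without it the differences were -304 bp in width, -1.31 in enrichment and 6.5 in number, and without -MET replicate 2 they were -639 bp, -6.61 and -3376.5.

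**Figure D3:**
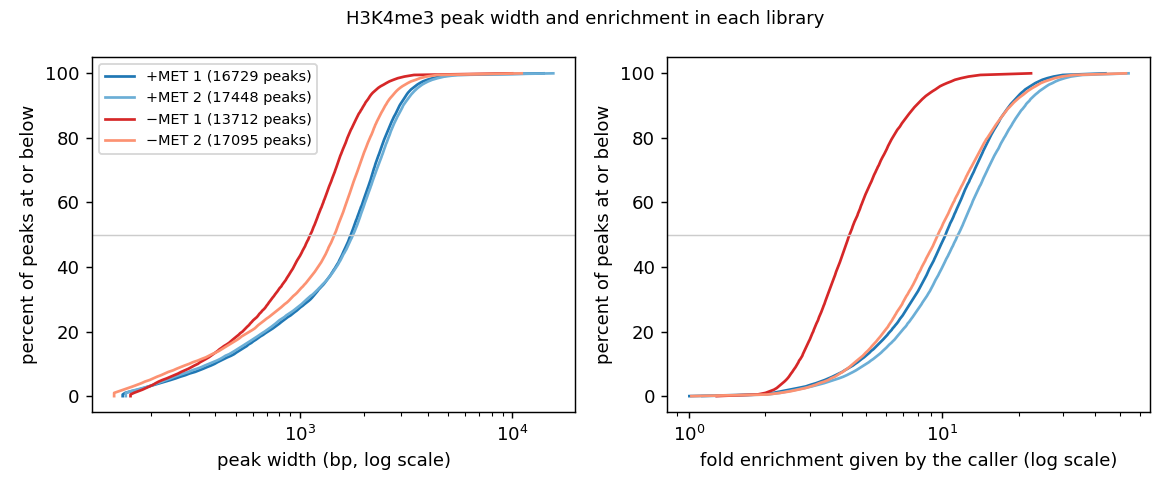
Percent of the peaks of each library (y axis) at or below a given width in bp (left) or fold enrichment (right), on log scales, with 1 line per library and a grey line at 50%. Both -MET libraries cross that line at smaller widths (1121 and 1456 bp) than both +MET libraries (1739 and 1781 bp).

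The position of H3K4me3 was largely shared. The 4 lists merged into 18831 regions, of which 12985 (69.0%) held a peak in all 4 libraries and 2395 in all but -MET replicate 1. A peak in both +MET libraries and neither -MET library was found in 598 regions, and the opposite in 34. Between 74.8% and 93.7% of the peaks of a +MET library overlapped one of a -MET library, with a mean of 84.5%, against 92.0% and 96.3% between the +MET libraries and 77.0% and 99.7% between the -MET libraries. With peaks of q under 1e-10 alone that mean was 53.5%. At that cut 28.8% and 27.7% of the peaks of +MET replicates 1 and 2 overlapped -MET replicate 1, and 79.9% and 77.6% overlapped -MET replicate 2. The median -log10 q of -MET replicate 1 was 7.21, so the cut removed most of its peaks. At the 12257 regions with exactly 1 peak in each library, both -MET peaks were narrower than both +MET peaks in 84.1%. The median width change was -0.70 on the log2 scale in -MET replicate 1 and -0.24 in -MET replicate 2.

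Called peaks were narrower in every width class, though read depth is unknown and its effect on called widths was not tested. Peaks shared by all libraries were put in 4 classes by their width in +MET replicate 1 and compared with +MET replicate 2. In the narrowest class, 147 to 1482 bp, the median log2 width change was -0.94 in -MET replicate 1 and -0.23 in -MET replicate 2. In the widest, 2528 to 14029 bp, it was -0.67 and -0.26. The classes in between stood at -0.81 and -0.29, and at -0.72 and -0.29. With the +MET libraries exchanged, the narrowest class gave -0.80 and -0.14. The widest minus the narrowest class gave 0.27 in -MET replicate 1 and -0.03 in -MET replicate 2, so the libraries differed in sign.

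The 5 widest peaks of both +MET libraries (hg19, as placed in +MET replicate 1) were traced in all 4. The width in each other library is the total of its peaks that overlap the +MET replicate 1 peak. The first lay on chromosome 7 from 27200238 to 27214266, was 14029 and 14169 bp wide in +MET, and was split into 4 peaks of 9289 bp together in -MET replicate 1 and 3 peaks of 12660 bp in -MET replicate 2. A peak at TNRC18 on chromosome 7, from 5458646 to 5469969, measured 11324 and 11836 bp in +MET and 9975 and 11064 bp in -MET. One on chromosome 22, from 46464569 to 46473620, measured 9052 and 15570 bp in +MET and 3161 and 6582 bp in -MET, in 2 parts each. The 15570 bp peak reached beyond these positions, and -MET peaks wholly outside them were not counted. One on chromosome 17, from 79366301 to 79374585, measured 8285 and 8033 bp in +MET and 5640 and 7087 bp in -MET. The last, on chromosome X from 39951003 to 39958904, measured 7902 and 9580 bp in +MET and 2996 and 8509 bp in -MET. The gene tables name a gene for TNRC18 alone among these 5.

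**Figure D4:**
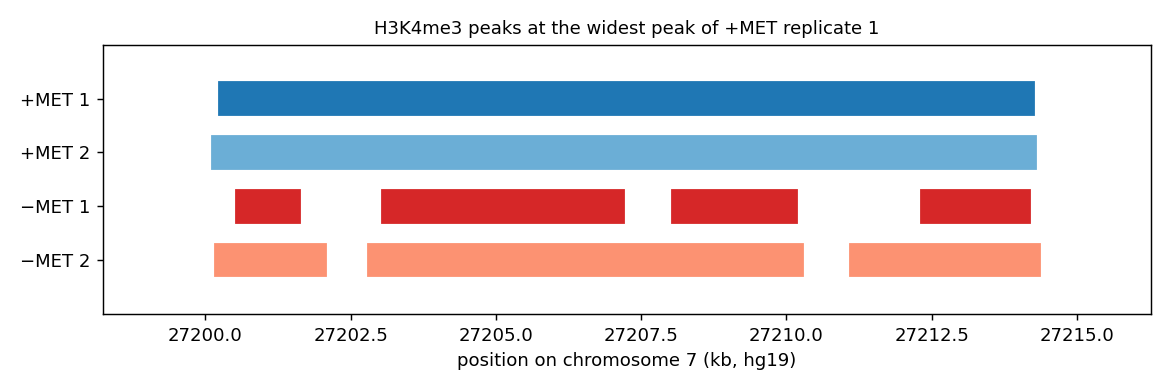
Peaks of each library (bars, 1 line per library) over the widest region on chromosome 7, with position in hg19 on the x axis. The single peak of each +MET library, 14029 and 14169 bp wide, is 4 peaks in -MET replicate 1 and 3 in -MET replicate 2.

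At genes, peak height was tested with limma. Both genes that passed were lower in -MET and are named for that reason, after their values were seen. LOC647323, an unnamed locus on chromosome 3 from 193720679 to 193721884, changed by -3.33 ± 0.62, from heights of 57.3 and 35.4 tags to 3.43 and 3.76 (limma adjusted p 0.0124). FAM27A, in a multi-copy family, with its peak on chromosome 9 from 45726695 to 45726880, changed by -3.51 ± 0.66, from 64.2 and 55.7 tags to 4.24 and 4.44 (limma adjusted p 0.0124). No gene was higher by limma, and 1834 of 10361 genes passed an unadjusted p of 0.05. The median height change of all genes was -0.845 on the log2 scale, and with each library centred on its median limma called 0 genes, with 619 at an unadjusted p under 0.05. Heights barely repeated between libraries: across genes the Pearson r of log2 height was 0.28 between the +MET libraries, against 0.94 for log2 width. Heights of consecutive peak entries over 1000000 bp apart correlated by 0.351 to 0.386, so the heights given for both genes above may not belong to these loci. None of the fixed lists was called on heights by camera, where the lowest adjusted p was 0.873 and 0 of 24 lists had an unadjusted p under 0.05; without -MET replicate 2 the replication-dependent histones were called higher, at 0.0257. On simulated heights limma recovered 3% of 100 genes changed by 2 on the log2 scale, so this count sets no limit on how many genes changed.

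**Figure D5:**
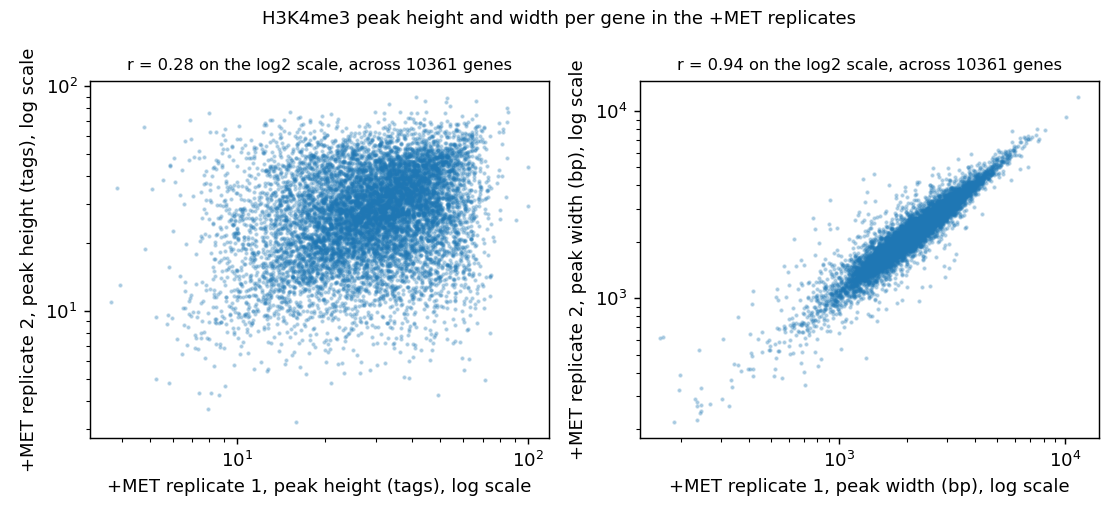
Height in tags (left) and width in bp (right) of the H3K4me3 peaks at genes in +MET replicate 1 (x axis) and +MET replicate 2 (y axis), on log scales, 1 point per gene. Widths follow the diagonal, with a Pearson r of 0.94 on the log2 scale, and heights do not, with 0.28.

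Peak width per gene, a measure chosen after the heights were seen, gave 39 lower genes and 0 higher ones in limma, with 2679 at an unadjusted p under 0.05. SSBP4 changed by -3.66 ± 0.50 on the log2 scale, SAMD10 by -1.77 ± 0.27 and PPM1B, a protein phosphatase gene, by -1.68 ± 0.24. SP1, a promoter-binding transcription factor gene, changed by -1.30, the adhesion receptor gene CD44 by -1.12 and the nuclear receptor gene NR4A1 by -1.10. With each library centred on its median limma called 0 genes, with 505 at an unadjusted p under 0.05. The count was 59 without -MET replicate 1, 9959 without -MET replicate 2, and 0 without either +MET library, where 167 and 97 genes passed an unadjusted p of 0.05. On these uncentred widths, camera called the replication-dependent histones (median -0.72 after centring each library, adjusted p 1.69e-04), ATF4 targets (-0.09, 0.00380) and immediate early genes (-0.15, 0.00559) as narrower than other genes, and interferon genes (0.20, 0.00380) as wider. With each library centred on its median, 1 list was called, as narrower. With an estimated correlation the adjusted p was 0.990 for each, and without -MET replicate 1 camera called 0 lists, with 1 of 24 at an unadjusted p under 0.05, against 7 lists without +MET replicate 1.

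Across 9312 genes measured in both assays, none of 4 correlations of H3K4me3 change with RNA change passed after adjustment. For height, Spearman's rho was 0.0024 (permutation p 0.816) and Pearson's r -0.0035 (permutation p 0.741), for heights that may not belong to their genes, as above. For width, rho was -0.00057 (permutation p 0.956) and r -0.0234 (permutation p 0.0232). Adjusted over these 4 tests, the p was 0.956 for the first 3 and 0.093 for the last, and genes are not independent replicates. Without -MET replicate 1 the rho of width was 0.0668. The median height change was -0.84, -0.86 and -0.84 at genes higher, lower and not passing in RNA, and the median width change -0.50, -0.50 and -0.49. Neither of the genes lower in height was among these 9312. Of 34 genes with narrower peaks tested in RNA, CD97, MYEOV, PPM1B, S100A6, SH3RF2 and TFE3 rose in RNA, where 4.24 were expected (Fisher's exact p 0.307, adjusted over the 2 overlaps 0.307). Only ANXA11 fell in RNA, where 6.04 were expected (Fisher's exact p 0.0218, adjusted 0.0435). The 34 genes came from uncentred widths, and with each library centred on its median 0 genes passed. Fisher's test also takes genes as independent, so this overlap is no evidence of a link. These heights and widths come from different libraries than the RNA, and both -MET ChIP libraries carried the lower values described above.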

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

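Settings other than the planned ones, and all settings of peak width per gene, were chosen after the data were seen. Count-based settings of H3K4me3 (size factors, library totals, count filters, DESeq2) were not run because its table is not counts.

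The RNA count stayed between 3961 and 5760 over the 7 settings that kept all libraries. DESeq2 called 4511 genes, 3941 of them shared with the 4127. Leaving out 1 library gave 1058 to 8807 genes; of the 1058 and the 1200 called without a -MET library, 1054 and 1187 were among the 4127, and without a +MET library 4118 and 4124 of the 4127 were kept. Of the 122 named genes that passed, DESeq2 kept 120, library totals 118, and the fits without -MET replicate 1 and 2 kept 86 and 82. MTRR, CTH and AMD1, which did not pass with all libraries, ran from -0.62 to 0.38, -0.72 to 0.80 and -0.34 to 0.43 without a +MET library, so their direction depended on which +MET library was kept. Genes that passed in neither setting are not counted as reversed.

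Camera called 13 fixed RNA lists, 12 to 13 over the count settings, 10 to 16 without 1 library, 0 with an estimated correlation (also 0 of the 4 lists added later), and fry called 9. Fry did not call the ATF4, p53, ribosome biogenesis and fibroblast lists, with adjusted p of 0.233, 0.118, 0.233 and 0.116. The fibroblast call of camera was also lost with library totals and with no filter, at an adjusted p of up to 0.0659. Height lists called were 0 in the settings with all libraries and 0 to 1 without a library.

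For height, centring and equal totals gave 0 genes in limma (619 and 586 at an unadjusted p under 0.05), a mean of at least 20 tags 1 gene, not one of the 2, and leaving out a library 0 to 1. For width, the 39 genes became 85 at an adjusted p under 0.1, 0 after centring and 0 to 9959 without a library. The 4 width lists became 0 with an estimated correlation, 1 after centring, 0 with fry and 0 to 7 without a library. The cause was not tested, except that a fit on fewer libraries takes its spread from the condition that keeps both.

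With the replicate number as a replicate block, which nothing shows to be a pairing (same-number correlation 0.0967 in RNA), 4123 genes (3770 shared) and 13 lists were called in RNA, 2 genes and 0 lists in height, 759 genes and 4 lists in width, and the rank correlation of height with RNA was 0.0031. With this block 11 p53 targets and 4 colon epithelial genes rose.

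The peak number difference ran from -3376.5 to 6.5 without a library, so its direction reversed without -MET replicate 1, and was -5879 with q under 1e-10. Width differences ran from -639 to -304 bp and enrichment from -6.61 to -1.31, below 0 in every setting run. The mean overlap of +MET peaks was 53.5% with q under 1e-10 and 69.8% with 50% of both peaks covered, and 76.5% to 92.5% without a library. The drops at q under 1e-10 and at 50% covered came mostly from -MET replicate 1. The widest minus the narrowest width class stayed between 0.06 and 0.13.

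The rank correlation of height with RNA ran from -0.0014 to 0.0060 without a library and was -0.0227 at genes that passed in RNA. For width it was -0.00057, -0.0339 at genes that passed in RNA, 0.0668 without -MET replicate 1 (permutation p 1e-05, the smallest they can give), -0.0162 without -MET replicate 2, -0.0138 without +MET replicate 1 and 0.0131 without +MET replicate 2. The cause of these reversals was not tested.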

Other observations

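The 4 gene lists of this part and its tests of explanations were chosen after the result was seen. The exact test of the peak widths and the camera test of the fibroblast list, both repeated here, had been planned.

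Some inflammatory and adhesion genes rose beyond the fixed lists. Of 18 NF-kB targets and chemokine genes, 12 rose and 1 fell in edgeR, or 14 and 1 adjusted over the list alone, with a median of 1.76, also with CCL20 at the bound of its interval. CXCL3 rose by 4.88, CXCL2 by 4.13, and the feedback inhibitors TNFAIP3 and NFKBIA by 2.74 and 1.83, whereas SOD2 changed by -1.21. Of 14 laminin, hemidesmosome and matrix genes, 10 rose, 0 fell and 4 did not pass, or 11 and 0 adjusted over the list alone, with a median of 1.79. In the same libraries 1 of 5 fibroblast markers and 3 of 4 endothelial markers passed as higher. Of these, THY1, KDR and VWF needed the -MET libraries to pass the count filter, as described above. The fibroblast list had a median of 1.18 and a camera adjusted p of 0.0299, or 0.679 with an estimated correlation. The laminin chain genes LAMB3 and LAMA3 rose by 3.37 ± 0.15 and 2.97, and PLAU, the urokinase gene, by 2.20. For the NF-kB and laminin lists camera gave adjusted p of 1.83e-06 and 9.73e-07, and 0.172 and 0.133 with an estimated correlation. Both lists were made after their folds were seen, so these p-values and the counts adjusted over the list alone are no evidence beyond the folds.

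Most chaperone genes and some tubulin genes fell. Of 20 cytosolic and mitochondrial chaperone genes, 19 fell and 1 did not pass, also adjusted over the list alone, with a median of -1.48. HSPA8 changed by -2.91 ± 0.56, the mitochondrial chaperonin genes HSPE1 and HSPD1 by -2.44 and -2.28, and HSP90AA1 by -2.23, while HSPA9 stood at -0.07. The +MET libraries differed for HSPA8, with 5721.5 and 1681.5 CPM in replicates 1 and 2, against 417 and 567 CPM in -MET. Of 10 tubulin genes, 5 fell and 0 rose, also adjusted over the list alone, with a median of -0.56; TUBA1B changed by -2.47 and TUBB by -1.68. Only 2 and 3 tubulin genes fell without -MET replicate 1 and without -MET replicate 2. Camera gave adjusted p of 2.51e-12 and 0.0174, and 0.172 for each with an estimated correlation. As both lists were made after their folds were seen, these p-values and the counts adjusted over the list alone are also no evidence beyond the folds.

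H3K4me3 peaks were lower and narrower in both -MET libraries. Fewer reads in -MET replicate 1 are argued against as the whole cause, as far as the lowest background stands for depth. Its lowest background, implied by height and fold enrichment, was 0.848 times the +MET mean while its median height was 0.393 times. For -MET replicate 2 the ratios of background and height were 0.591 and 0.689, so fewer reads could account for its lower heights. This measure is rough: the backgrounds of the +MET libraries stood at 1.106 and 0.894 times their mean. Only 0.875% of the peaks of -MET replicate 1 lay within 1% of its lowest background. The heights used may also be mixed between entries, as described below. Less H3K4me3 after methionine removal and a weak immunoprecipitation of -MET replicate 1 alone stay open and cannot be told apart, as the exact p of the widths was 0.3333, the smallest possible here. Although -MET replicate 2 was narrower than both +MET libraries at 84.2% of 12257 regions, 1 offset of that library would give this too.

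ATF4 targets were higher in +MET replicate 2 than in +MET replicate 1, by a median of 1.32 on the log2 scale. RNA of a -MET library mixed into it is argued against, since 31.25% of the ATF4 targets higher in -MET than in +MET replicate 1 exceeded the -MET mean and histone genes allowed a median share of 1.57%; a first comparison with immediate early genes (median share 6.79%, against 48.8% for ATF4 targets, with overlapping quartiles) had decided nothing. A swap of labels is argued against by the r of 0.993 between the -MET libraries, against at most 0.935 across conditions. An amino acid shortage in that +MET sample stays open: aminoacyl-tRNA synthetase genes, many of them ATF4 targets, had a median 0.31 above +MET replicate 1, at percentile 100 of 10000 matched lists, but the same list did not rise as a whole in -MET (median -0.07, 1 higher and 4 lower). Other lists differed too: p53 targets stood at percentile 100 (median 0.52), ribosome biogenesis at percentile 0 (-0.80) and ER stress genes at percentile 65.2.

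H3K4me3 heights did not repeat between libraries, with r of 0.248 between the +MET libraries at 12257 regions, against 0.953 for widths. Heights of consecutive entries over 1000000 bp apart correlated by at least 0.351 in every library. The upper end of the 95% range of permuted heights was at most 0.0917 over the libraries. Heights were thus not independent of their neighbours. As this compares entries within a library, it cannot tell how much of the disagreement between libraries was counting noise. Over 10 classes of region width, r between the +MET libraries was 0.174 in the narrowest and 0.382 in the widest. Heights mixed between neighbouring entries of the lists stay open too. The highest correlation of consecutive heights was 0.386, while those of widths stayed within 0.0687 of 0. Counting noise and mixing were not told apart. How this would have come about was not tested, and no biological explanation was tested.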
